A study of Homo sapiens with 6 samples.

How the data were processed

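SH-SY5Y neuroblastoma cells were infected by spinning them with lentivirus and 8 µg/mL polybrene, and cells carrying a hairpin were selected with 2 µg/mL puromycin from 48 hours after infection for 3 days, per the labels' protocols. Total RNA was extracted with Trizol, ribosomal RNA was removed with Ribo-Zero Gold, and strand-specific libraries were made with the NEBNext Ultra II Directional kit, per the labels' protocols. The series held 6 libraries: 2 with 1 hairpin against TARDBP, 2 with control hairpin 1 and 2 with control hairpin 2. The labels do not say whether the libraries of a hairpin came from separate cultures.

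The authors used bcl2fastq and STAR 2.5.2b with genome build hg19, per the submitters' processing notes. The deposited values were raw counts, 1 file per library, with 1 line per gene symbol and 1 per repeat subfamily named with its family and class, per the file headers, and all were whole numbers. The counting tool, the gene and repeat annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts on repeat families and on near-identical genes, such as the histone, heat shock and HLA genes, therefore depend on choices that are not known here, and antisense or overlapping genes cannot be separated. No coordinates are given, since the annotation used for hg19 was not used here. Library totals ran from 18605745 to 21698339 counts, and the mean share of counts on repeat families was 25.2% with the TARDBP hairpin and 24.1% and 20.8% with control hairpins 1 and 2.

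Genes and repeat families were analysed together in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1 for gene lists). Of 28953 genes and families, 5025 had no count, and 17163 passed edgeR's filterByExpr by hairpin group (minimum count 10, minimum total count 15). Libraries were scaled by TMM. One quasi-likelihood model with 3 groups was fitted to all 6 libraries, with 3 residual degrees of freedom, 5.41 prior degrees of freedom and a biological coefficient of variation of 10.5%. Changes with the TARDBP hairpin were computed against the mean of both control hairpins, against each alone, and between the control hairpins. P-values were adjusted by Benjamini and Hochberg over all genes and families tested, and an adjusted p below 0.05 was a call, written as rose, fell, higher or lower. Standard errors were computed as the absolute log2 fold change over the square root of the F statistic. CPM values were scaled by the TMM factors.

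There were 36 gene and family lists fixed before the data were examined, as were the model, the comparisons and the alternatives not named below as added. They covered TDP-43 targets, ALS genes, neuroblastoma identity, neuronal, stress, immune, proliferation, metabolic and repeat groups, and markers of other cell types. The 32 lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. With an estimated correlation camera rests on the 3 residual degrees of freedom, which leaves it little power. A missing call there does not show that a list stayed unchanged. Genes were named by a rule fixed beforehand. It took TARDBP, then the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 3 and with each knockdown library beyond all 4 control libraries, leaving out symbols of uncharacterised and small RNA genes. It took 6 and 6 in the same way between the control hairpins, up to 4 called members with the lowest p of each list with all of any count of 5 or fewer, all members of the repeat lists, and the 3 families with the lowest p in each direction. The members of lists that the text counts beyond this rule, and the HLA, imprinted and YAP and TEAD target genes of the closing section, were chosen after values were seen. Results for some genes that this rule would name are not reported here.

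The fitting code was tested on simulated data for the comparison with the mean of both controls, with 200 changed genes placed among counts drawn from the real means and library sizes. Over 16877 genes and families it recovered 48% of changes of 1.5-fold and 83% of changes of 2-fold, and 26 of 157 calls were of unchanged genes. In 10 further simulations over 16865 to 16899 genes and families, 45.3% and 76.1% were recovered, and on average 9.12% of calls were of unchanged genes (5.30 to 12.9%), above the nominal 5%. The share of false calls may therefore exceed the threshold with 2 libraries per group, the only size simulated. The simulated share does not carry over directly, since 200 genes were changed there and 8269 genes and families were called in the real comparison. In a simulated shift of 1 list over 16888 genes and families, camera called that list and 0 of 31 others. Genes were drawn independently of each other there, so it could not show false list calls that arise from correlation between genes.

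The alternatives were other scaling (library totals, median ratios), no low-count filter or at least 50 counts in 2 libraries, a test against a 1.5-fold change, limma-voom, DESeq2 1.42.0, only the libraries compared, genes alone, families alone, pooled controls, the replicate number as a block, and each library left out in turn. A correction for GC content, which 15369 tested genes had (94.9% of those tested, matched by symbol), and the single-control versions of the list and family tests were added after the data were seen. The groups of 2 libraries allow no test by other splits of the samples.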

Results

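RNA was sequenced from SH-SY5Y, a human neuroblastoma cell line with sympathetic neuron features, after lentiviral delivery of a short hairpin RNA against TARDBP or of either of a pair of control hairpins. TARDBP encodes TDP-43, an RNA-binding protein that is lost from the nucleus in most cases of amyotrophic lateral sclerosis (ALS). The 6 libraries formed 3 groups of 2, namely the TARDBP hairpin, control hairpin 1 and control hairpin 2. The values were read counts for 27961 genes and 992 families of repeated sequence, of which 16202 genes and 961 families had enough counts to be tested. Library totals were 20365395 and 19281358 counts with the TARDBP hairpin, 19111171 and 19924728 with control hairpin 1, and 18605745 and 21698339 with control hairpin 2. Libraries of one group correlated with Pearson's r of 0.989 to 0.990 across genes and families, which are not independent replicates, and libraries of different groups with r of 0.916 to 0.959. Levels are given below as CPM, counts scaled to library size, mean ± SD with n = 2 libraries per hairpin, and changes as log2 fold changes (log2FC) with their standard error (SE). No source used here says whether the 2 libraries of a hairpin came from separate cultures. The p-value of a gene or family therefore measures only the spread between these libraries, which may be technical. The camera p-value of a gene list at the preset correlation of 0.01 compares its genes with all other genes. It treats genes as nearly independent and does not measure the spread between libraries.

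TARDBP itself was lower in both knockdown libraries than in all 4 control libraries. Its counts were 365 and 462 with the TARDBP hairpin, 1587 and 1478 with control hairpin 1, and 1761 and 1730 with control hairpin 2. These corresponded to 18.9 and 24.0 CPM (21.4 ± 3.62), 80.9 and 72.4 CPM (76.6 ± 6.03), and 92.7 and 81.5 CPM (87.1 ± 7.92). Against the mean of both controls TARDBP fell by 1.93 on the log2 scale (SE 0.126, adjusted p = 1.68e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), to 26.2% of the control level (95% confidence interval from the fit 21.5 to 32.0%). It fell by 1.84 against control hairpin 1 (adjusted p = 3.19e-05) and by 2.02 against control hairpin 2 (adjusted p = 1.96e-05). Between the control hairpins the log2FC was 0.18 (adjusted p = 0.273).

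**Figure D1:**
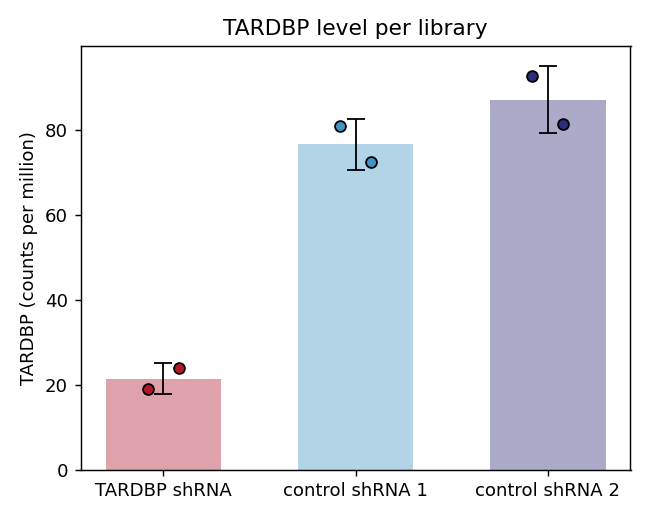
TARDBP level in CPM (vertical axis, from 0) by hairpin (horizontal axis), with each library as a point, the mean as a bar and the SD of n = 2 libraries as an error bar. The knockdown libraries lie at 18.9 and 24.0 CPM, below the lowest control library at 72.4 CPM.

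The comparison of the TARDBP hairpin with the mean of both control hairpins asks what changes in these cells when TARDBP is lowered. Cell-cycle genes fell with a median log2FC of -2.10, genes of the noradrenergic, axonal and synaptic programme fell, and targets of p53 rose at a preset correlation between genes. None of these lists was called with an estimated correlation (camera adjusted p = 0.345 to 0.380). The genes below were ranked by the naming rule, only among called genes with a mean log2 CPM of at least 3. Each knockdown library also had to lie beyond all 4 control libraries, so larger changes exist outside the rule. The largest rises were in KIAA1324, an estrogen-induced transmembrane protein gene, at 58.1 ± 5.52 CPM against 4.52 ± 0.235 and 2.47 ± 0.158 in control hairpins 1 and 2 (17.4-fold; log2FC 4.12, SE 0.110), and in CRTAC1, which encodes a secreted matrix protein, at 84.6 ± 11.9 CPM against 7.65 ± 0.571 and 8.64 ± 0.888 (10.4-fold; log2FC 3.38, SE 0.114). The other large rises under this rule were SAMD11 (log2FC 2.25), DNM3 (2.12), ABCA12 (2.10), SIAE (2.00), CCNG1 (1.96), SLC16A9 (1.94), CYBRD1 (1.91), SEL1L3 (1.87), PDGFRA (1.87) and HNMT (1.86). The largest falls were in the growth factor gene IGF2 (log2FC -6.72, SE 0.502) and the proliferation marker MKI67 (log2FC -6.61, SE 0.381). IGF2 stood at 0.337 ± 0.109 CPM against 101 ± 13.1 and 12.9 ± 7.43 CPM, and MKI67 at 1.01 ± 0.180 against 48.6 ± 23.1 and 203 ± 9.06 CPM. The next under this rule were MYBL2 (-6.21), the imprinted noncoding RNA gene H19 (-5.46), the collagen gene COL3A1 (-4.65), the retrotransposon-derived gene PEG10 (-4.64), HIST1H3B (-4.37), TOP2A (-3.89), RTL1 (-3.85), ELN (-3.84), DBH (-3.83) and PRR11 (-3.81). The adjusted p was 6.41e-04 for HIST1H3B and at most 3.69e-05 for each of the other 23. How reads were assigned between overlapping or antisense genes is not given in the sources used here, which leaves the levels of H19, IGF2 and RTL1 uncertain where other transcripts overlap them.

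In total 7860 genes were called, 3695 higher and 4165 lower, among which 2455 differed by at least 2-fold (1162 higher, 1293 lower). Genes and repeat families together gave 8269 calls (4102 higher, 4167 lower), and 9489 at an unadjusted p below 0.05. Without knockdown replicate 2 the rises numbered 2622 and the falls 3089. Of the 32 fixed gene lists with enough tested members, camera, a test of a list against all other genes, called 21 at a preset correlation between genes, 18 down and 3 up. None of the 32 was called when that correlation was estimated from these libraries (lowest adjusted p = 0.345, lowest unadjusted p = 0.0134). That version of camera rests on 3 residual degrees of freedom, so it could call few lists. Even the cell-cycle list, with 37 of 39 members lower, had an unadjusted camera p of 0.0675 there. The missing calls therefore do not show that the lists did not move. Fry, which asks only whether a list's own genes move one way, called 23. The number of called genes and families was 2572 when the 4 control libraries were pooled as one group, and 2462 when the test was against a 1.5-fold change.

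Genes of the cell cycle fell nearly as a whole. Of 39 tested members 37 fell (38 adjusted over the list alone) and 1 rose, with a median log2FC of -2.10 (camera adjusted p = 1.10e-29; adjusted p = 0.345 with an estimated correlation). Examples were MKI67, MYBL2, TOP2A and the replication factor gene MCM10 (log2FC -4.84, SE 0.257), at 0.726 ± 0.0712 CPM against 12.3 ± 3.11 and 35.8 ± 5.07 in control hairpins 1 and 2. The sole rise was TYMS, thymidylate synthase (log2FC 0.42, SE 0.103), which was not called without knockdown replicate 2 (log2FC 0.32, adjusted p = 0.0971). Among the replication-dependent histone genes 37 of 54 fell (39 adjusted over the list alone) and none rose, with a median of -1.36. Camera called the list (adjusted p = 1.31e-04), but not with an estimated correlation (0.760), and fry did not (0.198). Libraries of one hairpin lay apart in the list's median deviation from the mean of all 6 libraries. It was -0.48 and -1.15 with the TARDBP hairpin, -1.38 and -0.22 with control hairpin 1, and 1.15 and 2.16 with control hairpin 2. The fall came from the comparison with control hairpin 2, where 48 fell and the median was -2.55. In the comparison with control hairpin 1, 4 fell, 1 rose and the median was -0.10 (camera adjusted p = 0.963). HIST2H2BE fell against each control (log2FC -2.13 and -2.48), as did HIST1H3G (-4.03 and -6.90), although near-identical histone copies can share reads.

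Targets of p53, the DNA damage and stress regulator, moved the other way. Of 28 tested 17 rose (18 adjusted over the list alone) and 2 fell, with a median log2FC of 0.47 (camera adjusted p = 7.58e-08; adjusted p = 0.345 with an estimated correlation). The cyclin-dependent kinase inhibitor gene CDKN1A rose from 656 ± 47.5 and 675 ± 0.494 CPM in control hairpins 1 and 2 to 1540.1 ± 124 CPM (log2FC 1.21, SE 0.0820). ZMAT3 rose by 1.47 (SE 0.0798), SPATA18 by 1.62 (SE 0.0922) and CCNG1 by 1.96 (SE 0.0903). The falls were in the apoptosis genes PMAIP1 (log2FC -0.97) and BBC3 (-0.29), and BBC3 was not called without knockdown replicate 2 (-0.19, adjusted p = 0.277) or without any one of 3 of the control libraries.

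**Figure D2:**
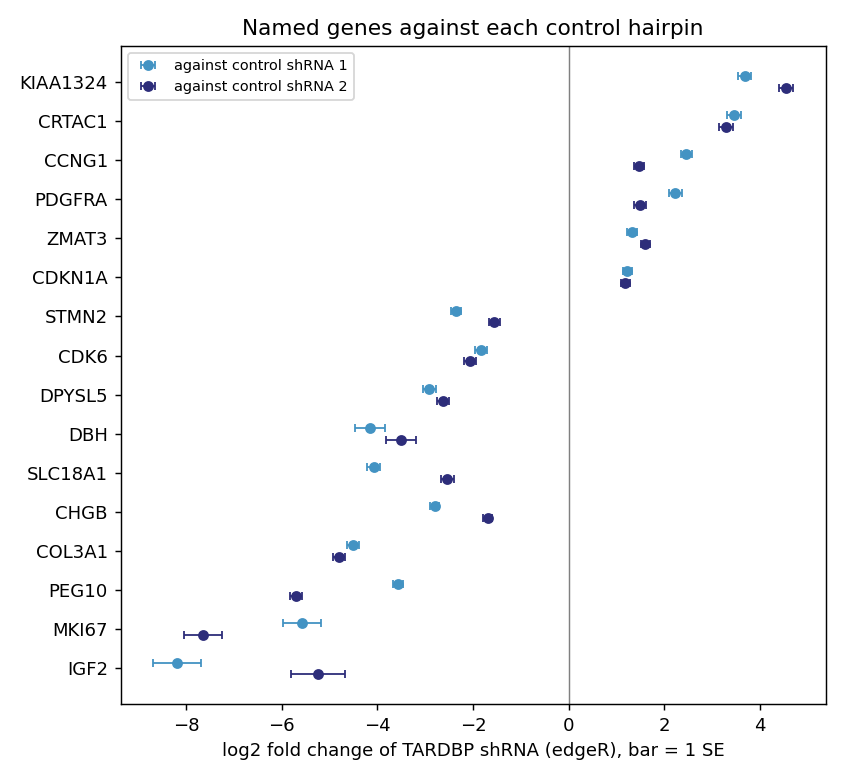
Change of named genes with the TARDBP hairpin against each control hairpin (horizontal axis, log2 fold change from edgeR), one gene per line on the vertical axis, with points for the fitted values, coloured by control hairpin, and bars for 1 SE (n = 2 libraries per hairpin). KIAA1324 lies at 3.68 and 4.56 and IGF2 at -8.20 and -5.24 against control hairpins 1 and 2.

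Genes that mark the noradrenergic identity of neuroblastoma fell. Of 25 tested 17 fell and 2 rose (17 and 3 adjusted over the list alone), with a median log2FC of -0.57 (camera adjusted p = 6.19e-11; adjusted p = 0.345 with an estimated correlation). DBH, the enzyme that makes noradrenaline, stood at 20.1 ± 7.64 CPM against 359 ± 100 and 228 ± 62.6 CPM. The vesicular monoamine transporter gene SLC18A1 (log2FC -3.31, SE 0.125), the granule protein gene CHGB (-2.25, SE 0.0891) and CYB561 (-2.10, SE 0.0837) fell too. The rises were in the transcription factor genes GATA3 (0.35), not called without knockdown replicate 1 (0.24, adjusted p = 0.103), and TFAP2B (0.28), which lost its call without any one of 5 of the 6 libraries. The axon and cytoskeleton list fell in 22 of 33 tested members and rose in 3 (24 and 3 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 6.19e-11; adjusted p = 0.345 with an estimated correlation). The growth cone gene GAP43 fell by 3.43 (SE 0.143), DPYSL5 by 2.77 (SE 0.123) and STMN4 by 2.14 (SE 0.129). ANK3 rose by 0.62, DPYSL3 by 0.48 and DPYSL2 by 0.43; DPYSL3 was not called without knockdown replicate 2 (0.25, adjusted p = 0.143), nor DPYSL2 without knockdown replicate 1 (0.28, adjusted p = 0.176) or control hairpin 2 replicate 1 (0.40, adjusted p = 0.0539).

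Synaptic vesicle and release genes fell in 19 of 39 tested members and rose in none, also when adjusted over the list alone (median log2FC -0.34, camera adjusted p = 3.26e-05; adjusted p = 0.380 with an estimated correlation). Examples were the vesicle protein genes SYP (log2FC -2.11, SE 0.119), SYN2 (-1.53, SE 0.137) and SV2C (-1.28, SE 0.0918). Ion channel and receptor genes fell in 14 of 32 and rose in 5, also adjusted over the list alone (median -0.23, camera adjusted p = 0.0314; adjusted p = 0.391 with an estimated correlation). The neuropeptide gene GAL fell by 3.02 (SE 0.265), while the potassium channel gene KCNQ5 rose by 1.18 (SE 0.0994). The call of this list was lost without knockdown replicate 2 (adjusted p = 0.0802) and against control hairpin 2 alone (camera adjusted p = 0.203).

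Lists of transcripts known to respond to loss of TDP-43 addressed whether the hairpin acts on them here. Genes that host cryptic exons, which are normally kept out of the transcript by TDP-43, fell in 17 of 25 tested members and rose in 3, also adjusted over the list alone (median log2FC -1.001, camera adjusted p = 2.08e-07; adjusted p = 0.345 with an estimated correlation). STMN2, a regulator of axon growth, stood at 143 ± 16.8 CPM against 732 ± 24.7 and 418 ± 23.8 in control hairpins 1 and 2 (log2FC -1.95, SE 0.0999). The synaptic release gene UNC13A fell by 1.87 (SE 0.158), INSR by 1.48 (SE 0.118) and PXDN by 1.36 (SE 0.0848). The rises were CYFIP2 (0.42), CEP290 (0.87), not called without knockdown replicate 2 (0.60, adjusted p = 0.0555), and EPB41L4A (0.48), not called without any one of 3 libraries. Between the control hairpins the same list was also lower in control hairpin 2 (13 of 25 lower, 4 higher, 14 and 4 adjusted over the list alone; camera adjusted p = 0.0317; adjusted p = 0.369 with an estimated correlation). Transcripts reported to change in level fell in 6 of 10 and rose in 1, also adjusted over the list alone (median -0.38, camera adjusted p = 0.00536; adjusted p = 0.345 with an estimated correlation). Among these the cell-cycle kinase gene CDK6 fell by 1.95 (SE 0.112), SREBF2 by 1.61 (SE 0.116) and RANBP1 by 1.24 (SE 0.159), and VPS4B rose by 0.56. The direction in which each was reported to change was not compared here. The fall of this list therefore does not show that the reported changes recurred. Counts per gene do not show splicing, so the list of transcripts reported to change in splicing is given by level alone. It fell in 8 of 12 and rose in 1, also adjusted over the list alone (median -0.50, camera adjusted p = 0.0256; adjusted p = 0.391 with an estimated correlation), with MADD at -1.05, MEF2D at -0.91, POLDIP3 at -0.84 and FNIP1 at 0.81. Its call was lost without knockdown replicate 1 (adjusted p = 0.0603) or control hairpin 2 replicate 1 (adjusted p = 0.0621), and against control hairpin 2 alone (camera adjusted p = 0.179). The hnRNP family, to which TDP-43 is related, fell in 15 of 27 and rose in 1 (16 and 2 adjusted over the list alone; median -0.29, camera adjusted p = 0.0222; adjusted p = 0.391 with an estimated correlation), with HNRNPA0 at -0.79 (SE 0.0919). It was not called against control hairpin 1 alone (median -0.15, camera adjusted p = 0.683). HNRNPH2 was the rise, at 0.32, and it was not called without either knockdown library (adjusted p = 0.0668 and 0.0726) or without control hairpin 2 replicate 2 (adjusted p = 0.0659).

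Fibroblast-type genes fell in 7 of 12 tested members and rose in 2, also adjusted over the list alone (median log2FC -1.18, camera adjusted p = 3.64e-04; adjusted p = 0.380 with an estimated correlation). COL3A1, COL5A1 (log2FC -2.20, SE 0.110) and PDGFRB (-1.74, SE 0.110) fell, while PDGFRA and DCN (2.43, SE 0.226) rose. The call of the list came from control hairpin 2, since it was not called against control hairpin 1 alone (median -0.51, camera adjusted p = 0.267). Extracellular matrix and adhesion genes fell in 15 of 33 and rose in 7 (16 and 7 adjusted over the list alone; median -0.32, camera adjusted p = 0.00739; adjusted p = 0.391 with an estimated correlation). COL4A2 (-2.27), the integrin genes ITGA5 (-1.90) and ITGA3 (-1.88) and the protease gene MMP2 (-1.44) fell, and ITGB3 rose (1.95). The matrix list against control hairpin 1 alone went the other way, with 11 higher, 9 lower and a median of 0.04 (camera adjusted p = 0.346). Mesenchymal neuroblastoma genes had 7 rises and 7 falls among 26, also adjusted over the list alone, with a median of 0.08 and a mean of -0.39. Camera did not call them (adjusted p = 0.137), while fry called them lower (adjusted p = 0.0396).

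Metabolic and stress lists mostly fell. Hypoxia and glycolysis genes fell in 20 of 28 and rose in 4, also adjusted over the list alone (median log2FC -0.53, camera adjusted p = 0.00107; adjusted p = 0.391 with an estimated correlation), with ENO1 at -1.71 (SE 0.187) and the glucose transporter gene SLC2A1 at -1.65 (SE 0.133). They were not called against control hairpin 1 alone (median -0.16, camera adjusted p = 0.354). Cholesterol synthesis genes fell in 15 of 24 and rose in 3 (16 and 3 adjusted over the list alone; median -0.40, camera adjusted p = 0.00226; adjusted p = 0.380 with an estimated correlation), with INSIG1 at -2.16 (SE 0.203) and HMGCS1 at -1.66 (SE 0.106). They were not called against control hairpin 1 alone (median -0.26, camera adjusted p = 0.179). Integrated stress response genes fell in 12 of 28 and rose in 3 (12 and 4 adjusted over the list alone; median -0.33, camera adjusted p = 0.0222; adjusted p = 0.380 with an estimated correlation), with SLC7A5 at -1.88 (SE 0.180) and its regulator ATF4 at -0.88 (SE 0.0982). After removal of a trend with GC content, tried after seeing the data, this list was not called (adjusted p = 0.0966), and against control hairpin 1 it held 7 rises and 7 falls, also adjusted over the list alone, and was not called (camera adjusted p = 0.987). Endoplasmic reticulum stress genes fell in 11 of 21 and rose in 4 (12 and 4 adjusted over the list alone; median -0.34, camera adjusted p = 0.0118; adjusted p = 0.345 with an estimated correlation), with MANF at -1.29 and DNAJB11 at -1.26. They were not called against control hairpin 1 alone (median -0.34, camera adjusted p = 0.254). Heat shock genes fell in 12 of 17 and rose in 2, also adjusted over the list alone (median -0.50, camera adjusted p = 0.0116; adjusted p = 0.391 with an estimated correlation), with HSPD1 at -1.06 (SE 0.0907) and HSPB8 at 1.46 (SE 0.109). This list was not called against control hairpin 1 alone (median -0.35, mean 0.20, camera adjusted p = 0.312). The other rise, CRYAB, was listed at 0 in both libraries of control hairpin 1 and lay at 2.15 ± 0.544 CPM with the TARDBP hairpin and 3.70 ± 0.501 CPM with control hairpin 2. Nuclear transport genes fell in 13 of 31 and rose in 4 (15 and 4 adjusted over the list alone; median -0.21, camera adjusted p = 0.0189; adjusted p = 0.345 with an estimated correlation), with the importin genes KPNB1 at -1.40 (SE 0.0758) and KPNA3 at -1.20 (SE 0.0870). They were not called against control hairpin 1 alone (median -0.10, camera adjusted p = 0.586). Ribosomal protein genes rose in 22 of 77 and fell in 4 (18 and 2 adjusted over the list alone), with a median of 0.26 and RPL34 at 1.16 (SE 0.105). Camera called them (adjusted p = 0.00659), but not with an estimated correlation (0.806), and fry did not (0.281). Their call was lost without knockdown replicate 1 (median 0.11, adjusted p = 0.232), and they rose against control hairpin 1 (45 higher, 1 lower) but not against control hairpin 2 (2 higher, 4 lower; camera adjusted p = 0.561).

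Other lists were not called by camera. Of these, fry called the interferon response list higher (adjusted p = 0.00672) and the ALS and frontotemporal dementia list lower (0.0235). Genes linked to ALS and frontotemporal dementia had 9 rises and 12 falls among 38 (10 and 12 adjusted over the list alone; adjusted p = 0.589), with the dynactin gene DCTN1 at -1.02, FIG4 at 0.94 and TMEM106B at 0.85. Oxidative stress genes under NRF2 had 7 rises and 10 falls among 36, also adjusted over the list alone (adjusted p = 0.458), and nuclear genes of oxidative phosphorylation 6 rises and 19 falls among 74 (5 and 18 adjusted over the list alone; adjusted p = 0.311), with ATP5F1B at -1.92. Interferon response genes had 11 rises and 4 falls among 31 (12 and 5 adjusted over the list alone; adjusted p = 0.255), with OAS1 at -1.44. Autophagy and lysosome genes had 10 rises and 14 falls among 39, also adjusted over the list alone (adjusted p = 0.587), with CTSA at -1.05 and ATG12 at 0.88. Factors that restrain retroelements had 9 rises and 10 falls among 35, also adjusted over the list alone (adjusted p = 0.620), with the DNA methyltransferase gene DNMT3B at -1.63. Nuclear long noncoding RNAs had 2 rises and 1 fall among 9, also adjusted over the list alone (adjusted p = 0.515), with GAS5 at 0.99, DLEU2 at 0.41 and KCNQ1OT1 at -0.52; DLEU2 was not called without either knockdown library (adjusted p = 0.0539 and 0.0803). Markers of other cell types were too few to test as lists. Of the microglial markers, TMEM119 fell (log2FC -2.52) and CD68 lay at -0.47 (adjusted p = 0.0785). Of the 4 oligodendrocyte and Schwann cell markers tested, PMP22 (-1.77) and CNP (-0.71) fell, MBP lay at 0.06, and 1 not named here rose. Of the 4 astrocyte markers, SOX9 rose (0.41) and GJA1 fell (-0.91), each losing its call without any one of 4 libraries, while SLC1A2 lay at 0.78 and FGFR3 at 0.09. Of the list of mitochondrially encoded genes, 2 were tested, and they were matched by the symbols RNR1 and RNR2, which have also been used for nuclear ribosomal RNA clusters, so their identity is uncertain. They took 12.2 ± 0.353% of all counts with the TARDBP hairpin, 9.04 ± 2.44% with control hairpin 1 and 6.27 ± 0.120% with control hairpin 2 (log2FC 0.72 for RNR1 and 0.76 for RNR2 against both controls). Ribosomal RNA was removed before sequencing, so these values describe what remained and do not by themselves show a change in the cells.

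**Figure D3:**
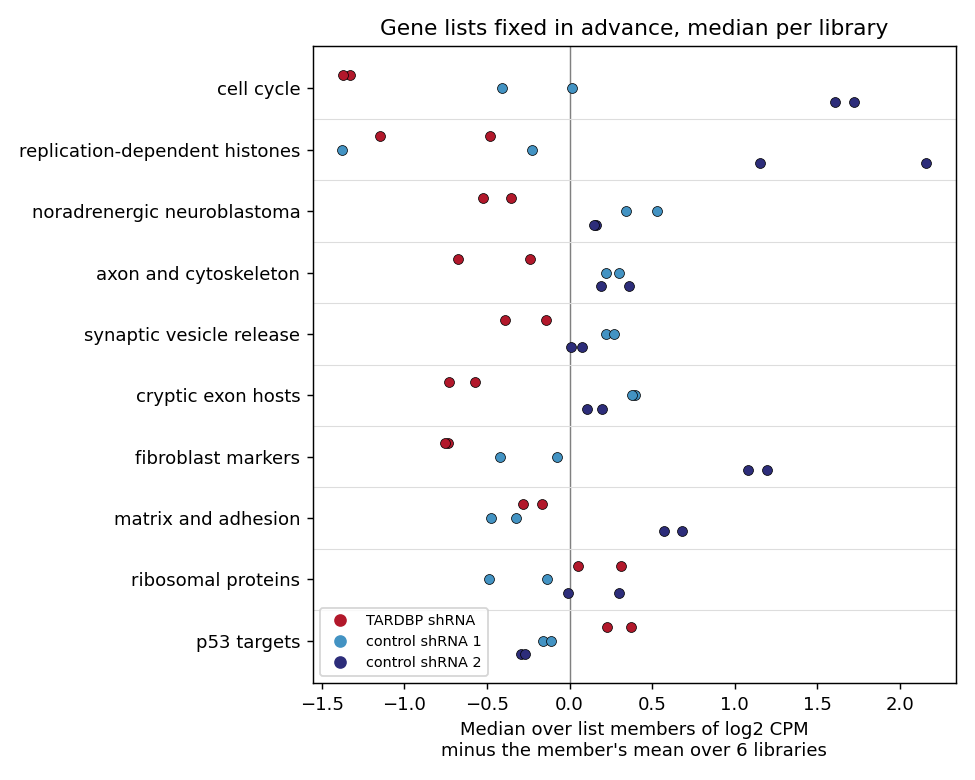
Median over the members of a fixed gene list of log2 CPM minus the member's mean over the 6 libraries (horizontal axis), one list per line on the vertical axis, with each library as a point coloured by hairpin. The cell-cycle list lies at -1.33 and -1.37 with the TARDBP hairpin, -0.41 and 0.01 with control hairpin 1 and 1.61 and 1.72 with control hairpin 2.

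The study's title concerns retrotransposon activation, and the families of repeated sequence were compared for that question. Most called families were higher with the TARDBP hairpin, most of them endogenous retroviruses, but the size of the rise depended on the control hairpin. Few of the young L1 and Alu families were called against the mean of both controls. Of 961 families 407 rose and 2 fell (PABL_B-int, log2FC -0.77, and X2_LINE, -0.55, the latter not called without either knockdown library or without 2 of the control libraries). The lowest p-values among the rises belonged to MER61-int (log2FC 0.88, SE 0.0759), L1M2a1 (1.34, SE 0.122) and HERVP71A-int (1.01, SE 0.0931). With families scaled by their own total in place of all counts, 146 rose and 89 fell. Against control hairpin 1 alone 157 rose and 2 fell, and against control hairpin 2 alone 580 rose and 2 fell. Without knockdown replicate 1, knockdown replicate 2 or control hairpin 2 replicate 2 the count of called families dropped from 409 to 209, 199 and 259. It was 59 with pooled controls and 15 when tested against a 1.5-fold change.

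Long terminal repeat (LTR) families, the remains of endogenous retroviruses, rose in 284 of 492 (median log2FC 0.34), and 120 of them rose against each control. Their median was 0.22 against control hairpin 1 and 0.46 against control hairpin 2. DNA transposons, which no longer move in humans, had medians of 0.02 and 0.28 over 200 families, and LINE families 0.02 and 0.40 over 145. The LTR median exceeded that of DNA transposons by 0.20 against control hairpin 1 (95% bootstrap interval over families 0.16 to 0.23) and by 0.18 against control hairpin 2 (0.15 to 0.21), a difference that no scaling of whole libraries can alter. Between the control hairpins it was 0.03 (0.01 to 0.06). These intervals leave out the spread between libraries, and the difference lay at -0.09 and 0.00 in the libraries of control hairpin 2 and at 0.11 and 0.15 in those of the TARDBP hairpin. The SINE median was 0.12 over 48 families, and 12 of 22 satellite families rose (median 0.50). The HERV-K and HERV-H list rose in 7 of 8, also adjusted over the list alone (median 0.40, camera adjusted p = 0.0189; adjusted p = 0.380 with an estimated correlation). HERVK-int rose against each control (log2FC 0.72 and 1.34; 80.6 ± 14.6 CPM against 49.1 ± 1.89 and 31.9 ± 3.74). Against control hairpin 1 alone 3 of the 8 rose (5 adjusted over the list alone) and the list was not called (camera adjusted p = 0.312). Of 8 young L1 families, 1 rose (0 adjusted over the list alone), L1PA8 at 0.24, which lost its call without any one of 4 libraries, and L1HS, the L1 family still active in humans, lay at 0.07 (SE 0.0711, adjusted p = 0.451). Of 8 young Alu families, 2 rose (1 adjusted over the list alone), AluYb9 at 0.72 (SE 0.132) and AluYg6 at 0.26, which lost its call without any one of the 6 libraries, and of 6 SVA families none rose or fell, also adjusted over the list alone. The young L1 families depended on the control, since 5 of 8 rose against control hairpin 2 (7 adjusted over the list alone; median 0.27, camera adjusted p = 0.114) and none against control hairpin 1, also adjusted over the list alone (median -0.03). Against the mean of both controls camera called neither the young L1 (adjusted p = 0.453) nor the young Alu (0.311) nor the SVA list (0.458). Fry called the young Alu list higher (adjusted p = 0.0396) but not the young L1 (0.101) or the SVA list (0.326). Families took 25.2 ± 0.772% of counts with the TARDBP hairpin, 24.1 ± 0.999% with control hairpin 1 and 20.8 ± 0.182% with control hairpin 2. Of these counts 7SK, a small RNA that is not a retrotransposon, took 3.65 ± 1.03%, 2.40 ± 0.397% and 2.17 ± 0.570% of all counts, in the same order. The repeat family MER11B took 0.555 ± 0.311%, 0.337 ± 0.185% and 0.660 ± 0.303%. Without both, the shares were 21.9 ± 0.291%, 21.9 ± 0.561% and 18.5 ± 0.546%, with no excess over control hairpin 1. The share without 7SK alone was not computed.

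**Figure D4:**
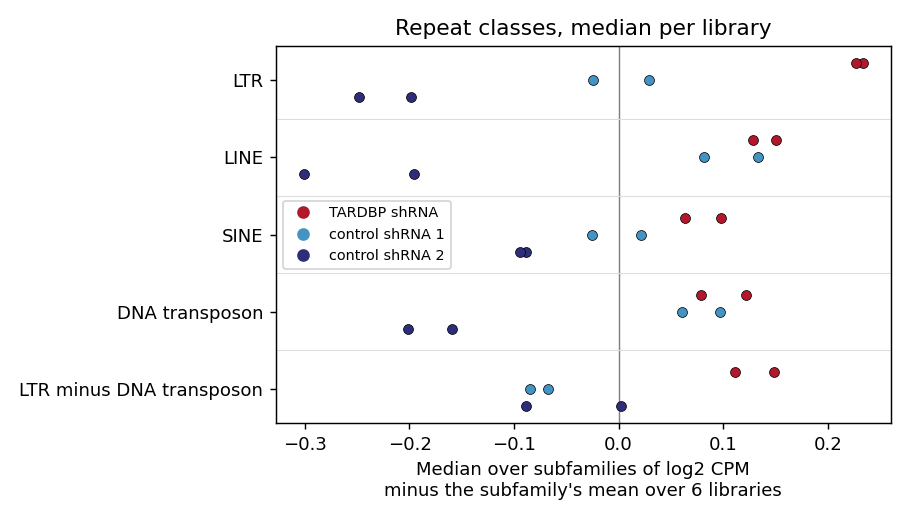
Median over the families of a repeat class of log2 CPM minus the family's mean over the 6 libraries (horizontal axis), one class per line on the vertical axis with the difference of LTR and DNA transposon medians on the last, and each library as a point coloured by hairpin. The LTR median lies at 0.23 and 0.23 with the TARDBP hairpin, -0.02 and 0.03 with control hairpin 1 and -0.25 and -0.20 with control hairpin 2.

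Setting the TARDBP hairpin against one control hairpin at a time asks which changes do not depend on the choice of control. Cell-cycle, noradrenergic, axonal, synaptic and cryptic-exon host genes fell, and p53 targets rose, against each at the preset correlation. With an estimated correlation none was called against either (adjusted p at least 0.210). Called cell-cycle genes were 29 lower and 2 higher against control hairpin 1 (30 and 2 adjusted over the list alone; median log2FC -1.22, camera adjusted p = 3.79e-10; adjusted p = 0.632 with an estimated correlation). They were 38 lower and 1 higher against control hairpin 2, also adjusted over the list alone (median -2.98, camera adjusted p = 2.66e-46; adjusted p = 0.210 with an estimated correlation). Noradrenergic genes fell in 17 and rose in 2 of 25 against control hairpin 1 (median -0.95, camera adjusted p = 3.58e-15), and fell in 11 and rose in 2 against control hairpin 2 (median -0.32, camera adjusted p = 2.30e-05), each also adjusted over the list alone. With an estimated correlation the adjusted p was 0.582 and 0.302. Axon and cytoskeleton genes fell in 22 and rose in 3 of 33 (median -0.76, camera adjusted p = 3.21e-09), and fell in 23 and rose in 1 (median -0.80, camera adjusted p = 2.65e-09), each also adjusted over the list alone. Their adjusted p with an estimated correlation was 0.582 and 0.210. Synaptic genes fell in 19 and rose in 2 of 39 (median -0.41, camera adjusted p = 1.48e-06), and fell in 18 and rose in 1 (median -0.27, camera adjusted p = 0.00440), each also adjusted over the list alone. For these the adjusted p with an estimated correlation was 0.582 and 0.456. Cryptic-exon hosts fell in 17 and rose in 2 of 25 (17 and 4 adjusted over the list alone; median -0.83, camera adjusted p = 4.70e-09), and fell in 16 and rose in 4 (17 and 4 adjusted over the list alone; median -0.85, camera adjusted p = 2.12e-04). The adjusted p with an estimated correlation was 0.306 and 0.210. Targets of p53 rose in 13 and fell in 3 of 28 against control hairpin 1 (median 0.21, camera adjusted p = 2.73e-05; adjusted p = 0.582 with an estimated correlation), and rose in 17 and fell in 1 against control hairpin 2 (median 0.56, camera adjusted p = 3.03e-07; adjusted p = 0.235 with an estimated correlation), each also adjusted over the list alone. KIAA1324 rose by 3.68 and 4.56, CRTAC1 by 3.47 and 3.29, STMN2 fell by 2.36 and 1.55, and TARDBP fell by 1.84 and 2.02. In total 7364 genes and families were called against control hairpin 1 (3615 higher, 3749 lower), and 8618 against control hairpin 2 (4120 higher, 4498 lower). The former count was 2337 higher and 2957 lower without control hairpin 1 replicate 1, and the latter 2151 higher and 3612 lower without control hairpin 2 replicate 2. Both comparisons called 4216 in the same direction (1816 higher, 2400 lower), and 508 in opposite directions. The shared rises numbered 1084 without knockdown replicate 2, 1119 without control hairpin 2 replicate 2 and 1190 without control hairpin 1 replicate 2. Of the 4216, 2734 were not called between the control hairpins (1323 higher, 1411 lower). Independent lists of these sizes would share 868 rises and 983 falls, and in 20 simulations with no change at all the mean and the maximum of the shared calls were both 0. These simulations made a mean of 1 and 0.700 calls per comparison, so they are no measure for lists of these sizes. Part of the excess may come from the knockdown libraries that both comparisons share, which a split would leave with 1 library per comparison and which were not split here.

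The comparison of the control hairpins with each other asks how far cells with different control hairpins differ when neither targets TARDBP. They differed in nearly as many genes as the knockdown did from the controls. Control hairpin 2 was higher in matrix, mesenchymal, cell-cycle and histone genes and lower in noradrenergic genes at the preset correlation. With an estimated correlation none of these lists was called (camera adjusted p = 0.242 to 0.539). The matricellular growth factor gene CTGF stood at 84.6 ± 16.4 CPM with control hairpin 2 and 1.09 ± 0.605 CPM with control hairpin 1 (log2FC 6.26, SE 0.278). ANKRD1 (4.77), the imprinted gene MEST (4.42), TGM2 (4.04), ACTG2 (3.86) and ADAM9 (3.73) were also higher. IGF2 (log2FC -2.96), INPP5D (-2.92), SERINC5 (-2.88), H19 (-2.80), FAM160A1 (-2.45) and HOTS (-2.30), which overlaps H19 and may share its reads, were lower. In all, 7073 genes were called (3912 higher and 3161 lower with control hairpin 2), with 2363 of them at least 2-fold apart (1623 higher, 740 lower), and with families the count was 7418. Among families 8 were higher and 337 lower. The total was 4328 without control hairpin 1 replicate 1, 4339 without control hairpin 2 replicate 2 and 2110 when tested against a 1.5-fold difference.

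Fry called 17 of 32 lists between the control hairpins, only in part the same as camera. Camera called 17 of 32, 14 higher and 3 lower in control hairpin 2, none with an estimated correlation (lowest adjusted p = 0.242, lowest unadjusted p = 0.0160). Without control hairpin 2 replicate 2 the lists were 14 higher and 1 lower. Cell-cycle genes were higher in 38 of 39, also adjusted over the list alone (median log2FC 1.86, camera adjusted p = 9.39e-26; adjusted p = 0.369 with an estimated correlation). MKI67 differed by 2.06 and TOP2A by 2.19. Histone genes were higher in 53 of 54, also adjusted over the list alone (median 2.43, camera adjusted p = 3.64e-14; adjusted p = 0.539 with an estimated correlation). Matrix and adhesion genes were higher in 25 and lower in 2 of 33, also adjusted over the list alone (median 1.17, camera adjusted p = 2.03e-18; adjusted p = 0.242 with an estimated correlation), with COL4A1 at 3.21. Mesenchymal neuroblastoma genes were higher in 20 and lower in 2 of 26 (22 and 2 adjusted over the list alone; median 1.10, camera adjusted p = 3.17e-12; adjusted p = 0.242 with an estimated correlation), with CYR61 at 3.23 and FN1 at 2.17. Fibroblast markers were higher in 11 of 12 (12 adjusted over the list alone; median 1.16, camera adjusted p = 2.51e-07; adjusted p = 0.369 with an estimated correlation).

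Smaller shifts between the control hairpins were found in further lists. Integrated stress response (17 higher, 2 lower of 28; median log2FC 0.69, camera adjusted p = 3.32e-06), hypoxia and glycolysis (20 and 4 of 28; 0.72, 1.23e-05), ribosomal protein (42 and 0 of 77; 0.46, 1.42e-05), oxidative phosphorylation (28 and 3 of 74; 0.39, 3.83e-04), hnRNP (17 and 0 of 27; 0.45, 0.00101) and nuclear transport genes (17 and 1 of 31; 0.36, 0.00174) were higher in control hairpin 2. Adjusted over the list alone the counts, in that order, were 17 and 2, 21 and 4, 45 and 0, 28 and 3, 18 and 0, and 17 and 1. With an estimated correlation the adjusted p of these lists, in that order, was 0.242, 0.369, 0.703, 0.703, 0.369 and 0.242. So were heat shock (8 and 0 of 17; 0.29, 0.0122), cholesterol synthesis (12 and 3 of 24; 0.27, 0.0150) and retroelement restriction genes (16 and 4 of 35; 0.25, 0.0335), with adjusted p = 0.476, 0.476 and 0.369 with an estimated correlation and counts adjusted over the list alone of 8 and 0, 12 and 3, and 16 and 5. Noradrenergic genes were lower in 14 and higher in 5 of 25, also adjusted over the list alone (median -0.39, camera adjusted p = 4.24e-05; adjusted p = 0.476 with an estimated correlation), with CHGA at -1.97 and SLC18A1 at -1.54. Cryptic-exon hosts (13 lower, 4 higher of 25, 14 and 4 adjusted over the list alone; median -0.45, camera adjusted p = 0.0317; adjusted p = 0.369 with an estimated correlation) and synaptic genes (16 lower, 6 higher of 39, 17 and 8 adjusted over the list alone; median -0.30, camera adjusted p = 0.0418; adjusted p = 0.703 with an estimated correlation) were lower as well. Targets of p53 were not called (4 higher, 9 lower of 28, also adjusted over the list alone; camera adjusted p = 0.269). The remaining lists tested between the control hairpins had camera adjusted p-values of at least 0.0580. Of these, fry called the endoplasmic reticulum stress (adjusted p = 0.00913) and interferon lists (0.0392) higher in control hairpin 2. It called the HERV-K and HERV-H (0.0170) and young L1 lists (0.0240) lower. Fry did not call the histone (0.0829), ribosomal protein (0.125), oxidative phosphorylation (0.0934) and synaptic lists (0.0985), which camera called. One hairpin targeted TARDBP and each hairpin had its own libraries, so an effect of lower TARDBP cannot be separated here from an effect of that hairpin or of its cultures.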

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

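The GC correction, the list and family counts against 1 control hairpin alone, and, for lists between the control hairpins, fry, library totals and the leaving out of libraries, were chosen only after the results were seen. Other scaling, both low-count filters, limma-voom, DESeq2, fits to only the libraries compared and the GC correction left each count of called genes within 1.5 times its value, and TARDBP was called lower under each alternative run for it. Tested against a 1.5-fold change, calls numbered 2462 for the TARDBP hairpin against both controls, 2622 against control hairpin 1, 2981 against control hairpin 2, 2110 between the control hairpins, 1201 in the same direction against each control, and 15 families, since small changes no longer count. With the controls pooled, 2572 genes and families and 59 families were called, as the difference between the hairpins then enters the spread. Families scaled by their own totals gave 235 calls (146 up, 89 down), and 159 were called against control hairpin 1 alone. With an estimated correlation 0 lists were called by camera in the main comparison and 0 between the control hairpins, at adjusted p-values of at least 0.242. That test rests on 3 residual degrees of freedom and could call few lists. For control hairpin 1 alone 10 lists were called; the integrated stress response list (median log2 change -0.0817) and the matrix list (median 0.0435) had the reverse direction by camera without a call, and the cause was not tested.

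Leaving out 1 library, with the lone library of its group assumed to vary like the others, gave 5711 to 7583 calls against both controls, 5294 to 7030 against control hairpin 1, 5763 to 8414 against control hairpin 2, 4328 to 7344 between the control hairpins and 2851 to 3440 in the same direction against each control. Families numbered 199 to 331, lists 19 to 21 and lists between the control hairpins 15 to 18, and the TARDBP change lay between -2.11 and -1.77. Total counts moved by over 1.5 times between the control hairpins without control hairpin 1 replicate 1 (4328) or control hairpin 2 replicate 2 (4339), and for families without knockdown replicate 1 (209), knockdown replicate 2 (199) or control hairpin 2 replicate 2 (259). Counts of rises alone also moved by over 1.5 times: against both controls from 4102 to 2622 without knockdown replicate 2, against control hairpin 1 from 3615 to 2337 without control hairpin 1 replicate 1, against control hairpin 2 from 4120 to 2151 without control hairpin 2 replicate 2, and against each control from 1816 to 1084, the lowest of 3 such moves. With the replicate number as a replicate block, calls numbered 7643 against both controls, 6745 and 7973 against control hairpins 1 and 2, 6670 between them, 3793 in the same direction, 342 families and 21 and 17 lists, none moved by over 1.5 times. The numbers do not pair the libraries, since deviations from the group means correlated at -0.228, -0.247 and 0.232 between groups. Over all alternatives, 3639 of 4148 repeats of the calls of 246 named genes and families kept their call, 509 lost it and 0 reversed; for 21 lists 230 of 272 kept it, 40 lost it and 2 reversed. The losses were uneven across the alternatives. With the control hairpins pooled, 141 of the 246 named genes and families lost their call and 105 kept it. Against a 1.5-fold change 102 lost it and 144 kept it. All 21 lists lost their call with an estimated correlation. Depth may limit genes near the filter, and 2 libraries per hairpin may limit the rest, which was not tested.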

Other observations

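The group tests here were chosen only after the results were seen, except that on long genes. Genes of the HLA class I pathway, which present peptides to T cells, were among the falls with the TARDBP hairpin. HLA-C stood at 10.8 ± 0.0673 CPM against 80.0 ± 0.268 and 68.7 ± 3.12 CPM in control hairpins 1 and 2 (log2 change -2.78, SE 0.0926, n = 2 each) and HLA-B fell by 2.93 (SE 0.257), although the HLA genes resemble each other and reads can be shared. Imprinted genes were also among the largest falls: besides IGF2, H19, PEG10 and RTL1, DLK1 stood at 9.72 ± 1.04 CPM against 147 ± 75.4 and 77.3 ± 36.8 CPM (log2 change -3.45, SE 0.410) and NNAT fell by 2.26 (SE 0.263). The imprinted genes SNRPN, PEG3 and MKRN3 rose, by 0.96 (SE 0.0926), 0.60 (SE 0.119) and 0.36 (SE 0.119). Of these, PEG3 was also called against each control hairpin alone. SNRPN lay at 0.08 against control hairpin 2 (edgeR adjusted p = 0.580) and MKRN3 at 0.18 against control hairpin 1 (edgeR adjusted p = 0.311).

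A hypothesis that imprinted genes fell as a group was tested without IGF2, H19, PEG10, RTL1 and DLK1, and without MEST, which had been seen to differ between the control hairpins; the median log2 change of the other 16 genes, NNAT among them, was -0.27 (camera adjusted p = 0.449), which leaves it open. The same test for HLA class I presentation gave a median of -0.30 over 10 genes, HLA-B among them (adjusted p = 0.165), again open. A hypothesis that targets of the growth regulators YAP and TEAD are higher in control hairpin 2 than in control hairpin 1 was tested without the members that raised it. The median of the other 18 genes was 0.74, with 11 higher and 3 lower (camera adjusted p = 6.58e-05; adjusted p = 0.118 with an estimated correlation), so they may differ as a group at the preset correlation only. The hypothesis that long genes fall with the TARDBP hairpin stays open, because the sign depended on the control. The median of 2881 protein-coding genes spanning at least 100000 bases differed from that of 10839 others by 0.0435 against both controls, -0.0248 against control hairpin 1 and 0.108 against control hairpin 2.

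The tests of the patterns below were chosen only after the results were seen, except that the fit with the replicate number as a block was planned. Repeat families rose with the TARDBP hairpin, most of them LTR families (284 of 407). As counted here, young L1 families did not lead the rise, since their median lay below that of the other L1 families (difference -0.11, with -0.07 to 0.09 for random sets). The random sets treat families as independent. Counts on families also depend on how reads with several matches were treated, which is not known. The difference therefore cannot exclude a rise of young L1 RNA. A general rise of reads that carry old repeats, such as unspliced RNA, is a candidate explanation for the rise against control hairpin 2. There immobile DNA transposons rose too (median 0.28). Against control hairpin 1 their median was 0.0198, which argues against a rise shared by all repeat classes. It cannot exclude a rise of reads from some classes only, since 8 of 22 satellite families also rose there (median 0.35). Whether the LTR excess follows from lower TARDBP or from this hairpin's cultures stays open, with 1 hairpin.

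The control hairpins differed in 7073 genes. Bias with GC content was argued against as the whole cause, since 7288 genes were called after its removal against 6861 before on the same 15369 genes, 6713 of them in both. Separate handling of each hairpin's cultures cannot be told apart from the hairpins, because each has its own libraries; with the replicate number as a block 6670 genes and families were called, which decides nothing. An effect of a control hairpin on cells, or a choice of cell subset during selection, might equally account for it and was not tested.

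Cell-cycle genes fell with the TARDBP hairpin, though the list was not called with an estimated correlation (camera adjusted p = 0.345, and 0.632 against control hairpin 1). For this list, high proliferation in control hairpin 2 alone was argued against, since 29 of 39 genes also fell against control hairpin 1 (median -1.22). GC content was argued against, since the median after its removal was -2.17 with 36 of 39 genes lower. The replication-dependent histone genes differed from this list, since against control hairpin 1 only 4 of 54 fell and 1 rose (median -0.10). Slower growth with lower TARDBP stays a hypothesis, which the cell-cycle list allows but the histone list against control hairpin 1 does not show. The histone list cannot decide it, since libraries of one hairpin lay apart. Its median deviation was -0.48 and -1.15 with the TARDBP hairpin and -1.38 and -0.22 with control hairpin 1. Counts of dividing cells with another TARDBP hairpin, or with TARDBP restored, would test slower growth. An effect of this hairpin, of its virus dose or of cell density stays open, untested.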
